A study of Mus musculus with 15 samples.

How the data were processed

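Poly(A) RNA was measured in 15 mouse libraries that form 5 groups of 3. The cells were E14 embryonic stem cells (mESCs) grown in 2i/LIF medium, in which inhibitors of MEK and GSK3 and the cytokine LIF hold the cells undifferentiated. Wild-type mESCs were left nontreated or given 500 nM dTAG-13 for 72 h. A knock-in line, NSD1-dTAG, carries a degron tag on NSD1, a histone H3K36 methyltransferase whose human gene is mutated in Sotos syndrome. dTAG-13 is a small degrader that joins an FKBP12-derived degron tag to cereblon, a substrate receptor of an E3 ubiquitin ligase, so that the tagged protein is ubiquitinated and degraded. Nontreated NSD1-dTAG mESCs formed 1 group, and embryoid bodies (EBs, cell aggregates that differentiate in suspension) grown for 6 days from that line with or without 500 nM dTAG-13 formed 2 groups. Wild-type EBs and dTAG-13-treated NSD1-dTAG mESCs were not analysed here. The labels call the 3 libraries of each group biological replicates and say nothing more of how they were grown, so the p-values measure the spread between these samples.

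Per the labels' protocols, ERCC Mix 1 spike-in RNA was added after extraction and libraries were made with a strand-specific kit. The authors deposited raw read counts per gene, not normalised, as 1 table per library. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR with no version, DESeq2 1.30.0 and the builds GRCm38.p6 and mm10. The counting settings and the annotation release are not given in the sources used here. Each table held 55471 gene IDs, 92 ERCC spike-ins and 1 count column, so which strand was counted is not known from the table. Of the gene IDs, 55230 matched GENCODE release M21 (GRCm38) without their version numbers, and this annotation gave symbols and coordinates. The other 241 IDs held at most 0.002% of a library's counts. Symbols shared by several IDs were replaced by the ID for 116 IDs. The ERCC counts stayed out of library sizes and tests. They made up 0.292% to 0.496% of all counts in the 9 mESC libraries and were 0 in all 6 EB libraries.

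Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, with TMM factors, the filter of filterByExpr and Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p below 0.05. Each of the 4 comparisons between groups used the libraries of its own groups, and the interaction used the 12 libraries of its 4 groups. Fold changes are on the log2 scale with the standard error of the fitted contrast. CPM values, each library's counts scaled to a common total, are means ± SD over 3 libraries and use the TMM factors of the comparison they stand in, except for Nsd1 and Mest in every library, which are plain CPM. Where all libraries of a group had 0 counts, the fold is a lower bound computed against 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% interval. Such intervals and floors cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

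Before the data were examined, the comparisons, tests, alternatives, a rule for naming genes and 30 gene lists were written down. The rule named, per comparison, the 8 highest and 8 lowest fold changes among called genes with a mean CPM of at least 1, no overlap between groups and a symbol that is not a numbered clone or model name. It added up to 4 called members of each list by p-value, or the 2 members with the highest CPM where none was called, and always Nsd1, Nsd2, Nsd3, Fkbp1a, Crbn, Pou5f1, Sox2 and Nanog. Some list members were left out of the text for length, in order of rank, and a few other named genes are not reported here. Lists were tested with camera from limma 3.58.1, with its preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. All p-values of lists were adjusted over the lists. The lists covered naive, core and formative pluripotency, germ layers and extraembryonic lineages, germ cells, methylation-sensitive germline genes, Hox and imprinted genes, chromatin enzymes, degrader machinery, signalling, stress and metabolism. Of the two-cell-like list no member reached the count filter in any comparison. The list holds 19 genes.

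Of the 249 genes that the rule named, 66 overlap exons of another annotated gene, 59 of them on the opposite strand and 13 on the same strand. Because the counted strand is not stated, counts of such genes are uncertain to the extent of the neighbour's reads. Partners are named in the text for some of these genes. Among the others, Nsd2, Atf5, Crbn and Col4a1 overlap Nelfa, Nup62, Trnt1 and Col4a2 on the opposite strand. Near-identical copies, such as the Sprr2a genes, are uncertain in the same way.

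Replicate numbers were tested for pairing before calls were compared. For wild-type against NSD1-dTAG mESCs the deviations of same-numbered libraries correlated at 0.58, 0.29 and 0.29, and for the EB groups at 0.23, 0.27 and 0.37, each library being closest to its own number. Those numbers were taken to pair the samples, and the fit with the replicate as a block is printed beside these comparisons where it moves a count by over 1.5 times. The labels do not say what the numbers share. No 2 libraries of a group were identical, and their counts differed beyond sampling noise in all 15 pairs within groups (chi-square over its degrees of freedom from 1.52 to 106). In each mESC group 1 pair came close to sampling noise. It was 1.67 for wild-type nontreated libraries 2 and 3, 1.52 for wild-type dTAG-13 1 and 2 and 2.17 for NSD1-dTAG 2 and 3. The other mESC pairs gave 13.8 to 106. Fits without the remaining mESC libraries, those that stand apart, thus rest on pairs with little spread, and their counts of calls may be too high.

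The procedure was tested on simulated counts with 200 changed genes per comparison, drawn for each gene independently and without shifts shared by the genes of a library. Among true 2-fold changes, edgeR recovered 88.1% for dTAG-13 in wild-type mESCs over 13611 genes and 74.6% for the NSD1-dTAG line against wild-type over 13669 genes. It recovered 77.6% for dTAG-13 in EBs over 14856 genes, 64.2% for EBs against mESCs over 13588 genes and 37.3% for the interaction over 15578 genes. The matching shares of 1.5-fold changes were 71.6%, 20.9%, 19.4%, 11.9% and 7.46%. False calls were 17 of 201, 2 of 138, 11 of 142, 11 of 130 and 4 of 92. The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, ERCC scaling (mESCs only), no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate block, a fit of all 15 libraries, a minimum 2-fold change and leaving out each library. A gene-length offset, that offset with the replicate block and a fit without libraries that stand apart were added after the data were seen and are marked so in the closing section.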

Results

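RNA-seq counts per gene were compared in wild-type mouse embryonic stem cells (mESCs), in NSD1-dTAG mESCs whose NSD1 protein carries a degron tag, and in day 6 embryoid bodies (EBs) of the tagged line. Wild-type mESCs were nontreated or had 500 nM dTAG-13 for 72 h, and EBs grew without or with 500 nM dTAG-13 for 6 days. Each of the 5 groups had 3 libraries. Gene counts per library summed to 27974979, 25910112 and 18704591 in wild-type nontreated mESCs and to 26798383, 24132609 and 23371917 in wild-type dTAG-13 mESCs. They summed to 29103958, 27812772 and 24562484 in nontreated NSD1-dTAG mESCs, to 26825756, 28085822 and 26906742 in nontreated EBs and to 25574544, 26792657 and 25896839 in dTAG-13 EBs.

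The first principal component held 86.7% of the variance and parted mESCs from EBs, and the next components held 3.48% and 2.69%. On component 3, libraries stood apart from others of their own group. NSD1-dTAG mESC library 1 scored 47.2 against -2.91 and -5.76, and wild-type nontreated library 1 scored 3.67 against -15.2 and -16.4. Wild-type dTAG-13 library 3 scored 14.5 against -13.7 and -15.9, nontreated EB library 3 scored 22.8 against -5.62 and -3.77, and dTAG-13 EB library 3 scored 23.5 against -16.8 and -15.7. The same 5 libraries had the shortest read-weighted exon length of their group, 4.99, 5.43, 5.25, 5.48 and 5.50 kb, and the highest share of counts on ribosomal protein genes, 7.98%, 5.76%, 5.88%, 6.34% and 6.57%.

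Nsd1 (ENSMUSG00000021488.8, GRCm38 chromosome 13, 55209782 to 55318325, plus strand) was transcribed in every library. Its plain CPM was 309, 396 and 387 in wild-type nontreated mESCs and 392, 393 and 248 in wild-type dTAG-13 mESCs. NSD1-dTAG mESCs had 163, 346 and 340 CPM, nontreated EBs 261, 243 and 209 CPM, and dTAG-13 EBs 329, 306 and 230 CPM. Group means were 364 ± 47.7, 344 ± 83.6, 283 ± 104, 238 ± 26.5 and 288 ± 51.9 CPM (SD, n = 3 each). In each group the lowest Nsd1 value came from the library that stands apart, so spread and fold changes depend on these libraries. Nsd1 was not called by edgeR in the main fit of any comparison. Some alternatives called Nsd1 or Fkbp1a between EBs and mESCs, as given below. The log2 fold change with dTAG-13 was -0.09 in wild-type mESCs (adjusted p = 1) and 0.26 in EBs (adjusted p = 0.351). dTAG-13 acts on the protein, which was not measured here, so these counts do not check its loss.

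**Figure D1:**
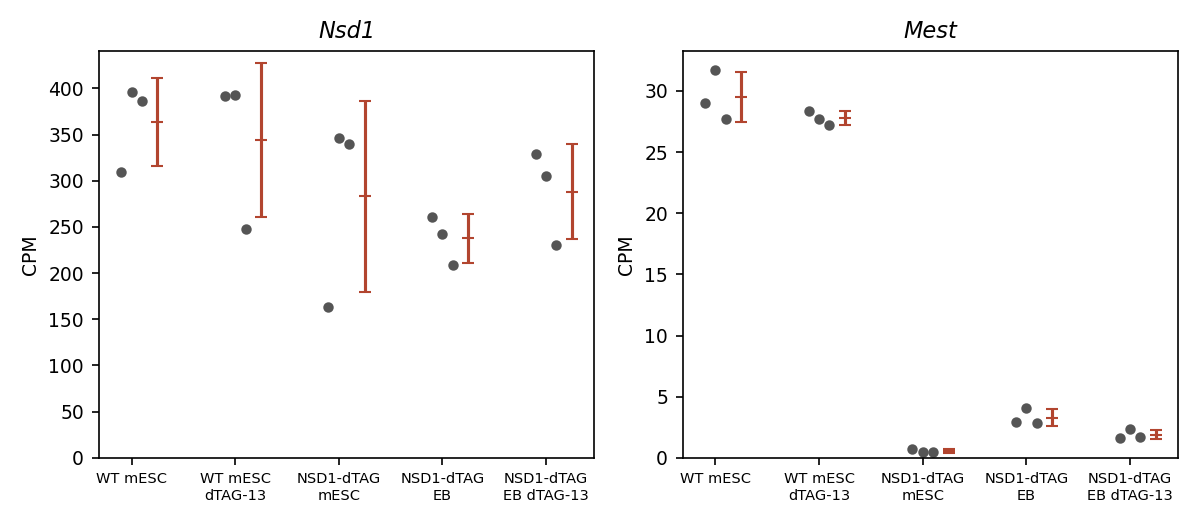
Plain CPM of Nsd1 and Mest in each library (grey points, in replicate order) with the group mean ± SD in red (n = 3), over the 5 groups. Nsd1 lies between 163 and 396 CPM, while Mest is above 27 CPM in all 6 wild-type mESC libraries and at most 4.06 CPM in the 9 libraries of the NSD1-dTAG line.

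To see whether dTAG-13 itself changes transcription where no tag is present, wild-type mESCs with and without the compound were compared. No gene was called. The pluripotency factors Pou5f1, Sox2 and Nanog differed by 0.04, 0.00 and 0.02 on the log2 scale, with Nanog at 592 ± 41.3 CPM without and 601 ± 61.5 CPM with dTAG-13 (SD, n = 3). Fkbp1a, which encodes the FKBP12 protein that the degron domain derives from, was at 369 ± 26.2 and 380 ± 30.0 CPM, and Crbn, which encodes the ligase receptor that dTAG-13 recruits, differed by -0.02. Nsd2 and Nsd3, which encode related H3K36 methyltransferases, differed by -0.02 and -0.04, and the adjusted p of all these genes was 1. Of 13784 genes tested, edgeR called 0, while 229 (1.66%) had an unadjusted p below 0.05. DESeq2 and limma-voom also called 0, with 79 and 243 genes at an unadjusted p below 0.05.

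Small shifts of 4 gene lists passed camera with its preset correlation in this comparison, although no member of them was called, over all genes or adjusted over the list alone. Wnt targets were shifted up (11 tested, median log2 0.09, adjusted p = 1.66e-06; adjusted p = 0.136 with an estimated correlation), with Axin2, a feedback inhibitor of Wnt signalling, at 0.09 and Notum at 0.06. Primitive streak and mesendoderm genes were shifted up (8 tested, median 0.02, adjusted p = 0.0221; adjusted p = 0.505 with an estimated correlation), with Sp5 at 0.27 and Lefty2 at -0.07. Formative and primed epiblast genes were shifted down (9 tested, median -0.18, adjusted p = 0.00509; adjusted p = 0.505 with an estimated correlation), with Dnmt3b at -0.02 and Zic2 at -0.18. Glycolysis and hypoxia genes were shifted down (14 tested, median -0.04, adjusted p = 0.00509; adjusted p = 0.589 with an estimated correlation), with Pkm and Aldoa both at -0.03. Leaving out wild-type nontreated library 1 and wild-type dTAG-13 library 3, which stand apart, gave 16 called genes, 4 higher and 12 lower, with Zic2 at -0.22 (adjusted p = 0.044). In that edgeR fit 893 of 13861 genes had an unadjusted p below 0.05, but the pairs left in it differed little beyond sampling noise.

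To see what the knock-in line brings with it before any degrader, nontreated NSD1-dTAG mESCs were compared with nontreated wild-type mESCs. The largest difference was Mest (ENSMUSG00000051855.15, chromosome 6, 30723547 to 30748465, plus strand), an imprinted gene expressed from the paternal allele. It fell 51.0-fold, from 28.9 ± 2.09 to 0.560 ± 0.172 CPM (log2 -5.67, SE 0.18, adjusted p = 1.57e-04). In plain CPM Mest stood at 29.5 ± 2.03 in wild-type mESCs and 0.546 ± 0.153 in NSD1-dTAG mESCs, and the overlapping antisense neighbour Copg2 had 85.6 CPM in the latter. In EBs of the line Mest was at 3.26 ± 0.69 CPM without and 1.88 ± 0.38 CPM with dTAG-13 (edgeR, log2 -0.81, adjusted p = 0.0829; adjusted p = 0.0328 with the replicate block). Fkbp6, a cochaperone of the meiotic piRNA pathway, fell from 7.26 ± 0.455 to 1.67 ± 0.00891 CPM (log2 -2.12, SE 0.11, adjusted p = 0.00259).

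Among the other largest falls were the oligodendrocyte transcription factor gene Myrf at log2 -2.16 (adjusted p = 0.0241), the arrestin gene Arrb1 at -2.10 (adjusted p = 0.0148) and the neural adhesion gene Nrcam at -2.04 (adjusted p = 0.0113). Cd109, Miip and Tspan7 fell by 1.89, 1.83 and 1.80 on the log2 scale. The largest rises were Synpo2l at 2.04 (SE 0.21, adjusted p = 0.0123, 0.515 ± 0.0885 to 2.18 ± 0.31 CPM) and the homeobox gene Meis2 at 1.37 (adjusted p = 0.0113, 14 ± 2.16 to 36.1 ± 2.66 CPM). Msc, a bHLH transcription factor gene, rose by 1.3 on the log2 scale, Ly6a by 1.31, Nkx6-3 by 1.17, and Ube2l6 and Tspan32 by 1.35 and 1.33. Pou5f1, Sox2 and Nanog differed by 0.19, 0.10 and 0.21 and were not called, nor were Fkbp1a at 0.11, Crbn at 0.09, Nsd1 at -0.31, Nsd2 at -0.19 and Nsd3 at -0.13. Nsd1 had 163 plain CPM in NSD1-dTAG library 1, which stands apart, against 346 and 340 in libraries 2 and 3.

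Methylation-sensitive germline genes, which promoter DNA methylation keeps silent in somatic cells, were lower in the NSD1-dTAG line. Of 14 tested, 4 fell and 0 rose, or 11 and 0 adjusted over the list alone (camera, adjusted p = 1.10e-12; adjusted p = 0.112 with an estimated correlation). Over all genes, 6 fell with the replicate block and 10 with the block and a gene-length offset, and without the libraries that stand apart 10 fell and 1 rose, Tex19.1 at 0.15. Leaving out any wild-type library or NSD1-dTAG library 2 ended all 4 calls, and without NSD1-dTAG library 3 there was 1 fall. The piRNA pathway gene Piwil2 fell from 7.12 ± 0.50 to 2.2 ± 0.19 CPM (log2 -1.69, adjusted p = 0.00844) and Sohlh2 by 0.88, Dazl by 1.00 and Mov10l1 by 0.89 on the log2 scale. Imprinted genes had 2 falls among 22 tested, 3 over the list alone, or 4 falls and 1 rise with the replicate block (adjusted p = 0.00114; adjusted p = 0.193 with an estimated correlation). Besides Mest this was the neuronal proteolipid gene Nnat, with 1 count over the 3 NSD1-dTAG libraries and a ratio of 43.7 (95% counting interval 7.85 to 1.73e+03).

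Formative and primed epiblast genes had 2 falls among 9 tested, 3 over the list alone (camera, adjusted p = 0.00399; adjusted p = 0.202 with an estimated correlation). They were Dnmt3a, a de novo DNA methyltransferase gene, from 22.8 ± 2.41 to 10.4 ± 2.07 CPM (log2 -1.14, adjusted p = 0.0265), and Lef1 at -0.62. Surface ectoderm genes had 2 falls among 9, also 2 over the list alone, Tfap2c at -0.68 and Cldn6 at -1.25 (adjusted p = 0.00667; adjusted p = 0.202 with an estimated correlation). Glycolysis and hypoxia genes had 1 rise among 14, or 4 over the list alone, the glucose transporter gene Slc2a1 at 0.45, and 5 rises with the replicate block (camera, adjusted p = 1.81e-04; adjusted p = 0.260 with an estimated correlation). Naive pluripotency genes had 1 rise among 15, Klf5 at 0.55, or 4 rises and 1 fall over the list alone and 2 rises and 1 fall with the replicate block (adjusted p = 0.0236; adjusted p = 0.238 with an estimated correlation). Hox genes were shifted up with 0 calls among 8, or 1 over the list alone (adjusted p = 0.0140; adjusted p = 0.238 with an estimated correlation), with Hoxc12 at 0.67. Integrated stress response genes were shifted down with 0 calls among 15, or 1 fall over the list alone or with the replicate block (adjusted p = 0.0223; adjusted p = 0.253 with an estimated correlation), with Psat1 at -0.25. In lists that camera did not call, En2 rose by 0.74 and Egr1 and Nes fell by 0.92 and 1.02 on the log2 scale.

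In all, edgeR called 259 of 13895 genes, 76 higher and 183 lower, 110 of them at least 2-fold, and 785 with the replicate block, among them all 259. Only 1 gene was called with ERCC scaling, under which the median log2 fold change of all genes was -0.0993 in place of 0.0118, and 3, 2 and 3 without wild-type library 1, 2 or 3. Without NSD1-dTAG library 1, 2 or 3 the count was 1248, 1 and 12, and without both libraries that stand apart (wild-type 1 and NSD1-dTAG 1) it was 3123. The pairs left in the latter fit differed little beyond sampling noise (chi-square over its degrees of freedom 1.67 and 2.17). The excess of falls varied in the larger counts. It was small without NSD1-dTAG library 1 (608 higher, 640 lower) and with the block and a gene-length offset (612 and 776), and turned without both libraries that stand apart (1587 and 1536). It stayed clear with the replicate block (292 and 493) and with DESeq2 (232 and 404). Of 35 named calls, 33 ended without each wild-type library in turn, 34 and 30 without NSD1-dTAG library 2 and 3, and 34 with ERCC scaling, but Mest was called in all 17 alternatives (largest adjusted p = 0.0038). Both mESC comparisons share the wild-type nontreated libraries. Their fold changes correlated at 0.343 across 13646 genes, which are not independent replicates, where unchanged groups simulated against those controls gave 0.509 (0.490 to 0.529). The covariance was 0.0184 against a simulated 0.0225. Calls shared by both were 0 by construction, since dTAG-13 in wild-type mESCs called none, and say nothing of agreement.

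To describe what day 6 of EB formation changes in this line, nontreated EBs were compared with nontreated NSD1-dTAG mESCs. Of 15 naive pluripotency genes 14 fell, while 10 of 10 formative and primed epiblast genes, 12 of 14 primitive streak and mesendoderm genes and 16 of 20 extraembryonic endoderm genes rose. These lists passed camera with its preset correlation but not with an estimated correlation (adjusted p of at least 0.194). Klf4 fell from 385 ± 4.12 to 14.2 ± 4.39 CPM (log2 -4.76, SE 0.24, adjusted p = 1.74e-06), while the epiblast gene Otx2 rose from 6.73 ± 0.544 to 133 ± 8.77 CPM (log2 4.30, SE 0.13, adjusted p = 3.48e-07). The mesoderm transcription factor gene T rose from 17.5 ± 0.60 to 239 ± 111 CPM and Eomes from 16.6 ± 2.19 to 175 ± 64.0 CPM. Pou5f1, Sox2 and Nanog fell by 0.78, 0.93 and 1.02 on the log2 scale and remained at 658 ± 143, 337 ± 24.2 and 339 ± 21.2 CPM. Nsd2 rose from 79.8 ± 13.8 to 204 ± 25.1 CPM (log2 1.36, adjusted p = 1.51e-04), Nsd3 by 0.49 and Crbn by 0.42. The calls of Nsd3 and Crbn ended with a gene-length offset (log2 0.19 and 0.24, adjusted p = 0.117 and 0.0524). That of Nsd3 also ended with the replicate block and in 4 of 6 fits that left out a single library (largest adjusted p = 0.155). Nsd1 at -0.39 and Fkbp1a at -0.09 were not called. With a gene-length offset, without NSD1-dTAG mESC library 1 and without the libraries that stand apart, 1 of them was called in each case.

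Several genes had 0 counts in all NSD1-dTAG mESC libraries. The carbonic anhydrase gene Car4 was at least 3068-fold higher in EBs (119 ± 18.4 CPM), the retinoic acid hydroxylase gene Cyp26a1 at least 2957-fold, Lhx1 at least 2666-fold, Cer1 at least 1340-fold, Pcdh7 at least 1101-fold and Psmb8 at least 954-fold. Fgf5, an epiblast growth factor gene with 1 count over the 3 mESC libraries, reached 192 ± 16.4 CPM (ratio 1.49e+04, 95% counting interval 2.67e+03 to 5.87e+05). In the other direction Hoxc12 was at least 98.7-fold and Srarp at least 57.6-fold lower. Trpm1 fell from 51.5 ± 3.94 to 0.128 ± 0.0425 CPM and Accsl from 53.5 ± 1.5 to 0.220 ± 0.101 CPM. Nkx6-3, Apol6 and Fcgr2b had ratios of 871, 515 and 430, with counting intervals of 241 to 7.19e+03, 142 to 4.25e+03 and 77.1 to 1.70e+04.

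By list, naive pluripotency genes had 14 falls and 1 rise among 15 (camera, adjusted p = 4.22e-10), formative and primed epiblast genes 10 rises among 10 (adjusted p = 9.32e-13) and extraembryonic endoderm genes 16 rises and 2 falls among 20 (adjusted p = 1.36e-09). In the latter, the basement membrane collagen gene Col4a1 rose by 6.58 and the endocytic receptor gene Cubn by 9.90 on the log2 scale. Primitive streak and mesendoderm genes had 12 rises and 1 fall among 14 (adjusted p = 3.53e-04), definitive endoderm genes 8 rises among 10 (adjusted p = 0.00468), surface ectoderm genes 7 among 9 (adjusted p = 1.25e-06), trophoblast genes 8 among 9 (adjusted p = 0.0309) and mesenchyme genes 9 rises and 2 falls among 12 (adjusted p = 7.96e-04). Imprinted genes had 20 rises and 2 falls among 27 (adjusted p = 2.05e-04), with Sgce at 3.75, Cdkn1c at 2.77 and Ndn at 2.99. p53 targets had 13 rises and 4 falls among 21 (adjusted p = 0.0309) and FGF and ERK targets 7 rises and 1 fall among 12 (adjusted p = 0.0127). Falls prevailed among Hox genes, with 7 and 1 rise among 9 (adjusted p = 0.00258), cholesterol synthesis genes, with 12 among 14 (adjusted p = 0.0168), and unfolded protein and heat shock response genes, with 7 among 12 (adjusted p = 0.0449). Camera did not call paraxial mesoderm genes, with 8 rises and 1 fall among 9 (adjusted p = 0.0880), neural crest genes, with 6 and 2 among 9 (adjusted p = 0.115), neuroectoderm genes, with 7 and 4 among 13 (adjusted p = 0.627), or lateral and cardiac mesoderm genes, with 7 and 4 among 11 (adjusted p = 0.705). Adjusted over the list alone, surface ectoderm rises were 8 and trophoblast rises 9, and the other counts did not differ. None of the 14 called lists passed with an estimated correlation (adjusted p of at least 0.194).

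Of 15193 genes, edgeR called 9037, 5035 higher and 4002 lower, 5290 of them at least 2-fold. With a gene-length offset 5059 were higher and 5065 lower. Stage was compared across libraries that also differ in ERCC counts, which were 0 in all EB libraries for a reason not known here, and in the share of mitochondrial counts, 1.81% to 2.05% in mESCs and 0.827%, 0.425% and 0.199% in nontreated EBs. The median fold change of genes on chromosome X lay 0.36 above that of other chromosomes.

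**Figure D2:**
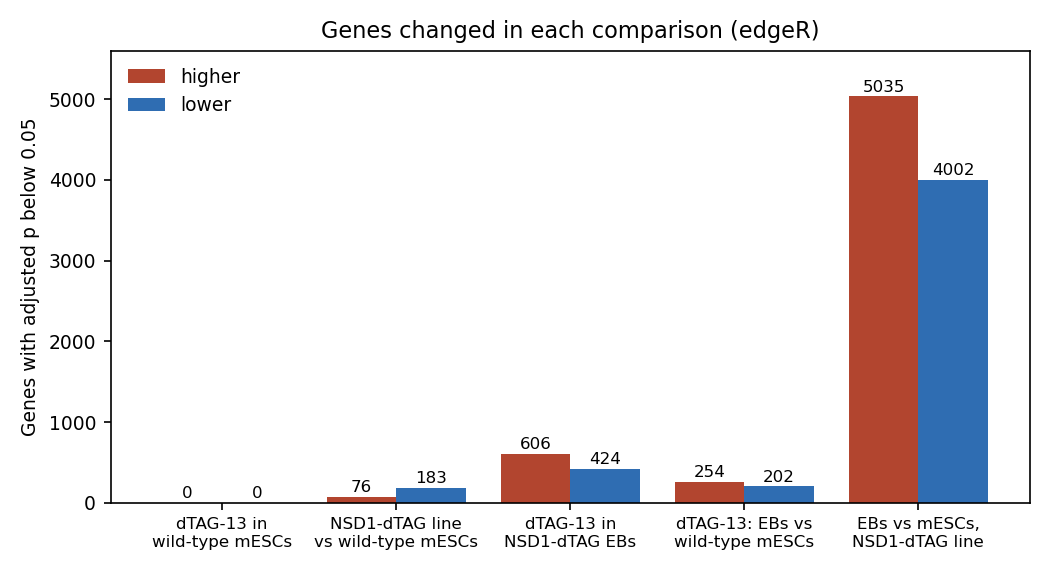
Number of genes called higher (red) or lower (blue) by edgeR at an adjusted p below 0.05 in each of the 5 comparisons. The counts run from 0 for dTAG-13 in wild-type mESCs to 5035 higher and 4002 lower for EBs against mESCs, with 606 higher and 424 lower for dTAG-13 in EBs.

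To see what dTAG-13 changes during differentiation of the tagged line, EBs grown for 6 days with the compound were compared with nontreated EBs. Of the genes tested, 10 of 14 primitive streak and mesendoderm genes, 7 of 12 Wnt targets and 7 of 15 naive pluripotency genes fell, and 11 of 16 methylation-sensitive germline genes rose. These lists passed camera with its preset correlation, and no list did with an estimated correlation (adjusted p of at least 0.283). The posterior streak homeobox gene Evx1 (ENSMUSG00000005503.8, chromosome 6, 52313498 to 52318378, plus strand) fell from 21.9 ± 12 to 0.928 ± 0.735 CPM (log2 -4.54, SE 0.60, adjusted p = 0.00870). Cdx2 (ENSMUSG00000029646.3, chromosome 5, 147300805 to 147307270, minus strand), a caudal homeobox gene of the posterior axis and trophectoderm, fell from 8.49 ± 3.37 to 0.279 ± 0.117 CPM (log2 -4.90, SE 0.43, adjusted p = 0.00310). The synaptonemal complex gene Sycp3 (ENSMUSG00000020059.9, chromosome 10, 88459569 to 88473236, plus strand) rose from 42.4 ± 9.99 to 169 ± 23.0 CPM (log2 1.99, adjusted p = 0.00311). Sycp3 had already risen without dTAG-13, from 3.08 plain CPM in NSD1-dTAG mESCs to 42.0 in nontreated EBs, a change that edgeR called. Evx1 overlaps the antisense Evx1os, and Sycp3 overlaps Chpt1, which had 10.7 CPM in dTAG-13 EBs.

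Nanog (ENSMUSG00000012396.12, chromosome 6, 122707489 to 122714633, plus strand), counted here in the naive list, fell from 359 ± 21.4 to 215 ± 25 CPM (log2 -0.74, SE 0.11, adjusted p = 0.0112). Pou5f1 at -0.12 and Sox2 at 0.02 were not called, nor were Nsd2 at -0.05, Nsd3 at 0.13, Fkbp1a at 0.07 and Crbn at -0.09. The largest rises were Tsga10ip at 3.53 (0.415 ± 0.151 to 4.88 ± 0.746 CPM, adjusted p = 0.00224), the melanosomal glycoprotein gene Gpnmb at 3.13 (0.963 ± 0.273 to 8.47 ± 1.21 CPM, adjusted p = 0.00194) and Cbln4 at 2.91 (adjusted p = 0.00628). Lrmp, which overlaps Casc1 on the opposite strand, rose from 2.44 ± 0.375 to 18.0 ± 2.53 CPM (log2 2.88, SE 0.18, adjusted p = 0.00134). The water channel gene Aqp6, Zfp783 (which overlaps Zfp956 on the same strand), the meiotic chromosome axis gene Hormad2 and the prostacyclin receptor gene Ptgir rose by 2.63, 2.61, 2.52 and 2.42. Among the largest falls were the apelin receptor gene Aplnr, from 35.7 ± 28.6 to 0.700 ± 0.705 CPM (log2 -5.65, adjusted p = 0.0127), and Rgs5, Optc, Cd36 and Samd3 at log2 -6.00, -5.31, -5.24 and -5.02. Sprr2a3, whose reads near-identical copies share, had a ratio of 74.7 (95% counting interval 25.6 to 362).

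Primitive streak and mesendoderm genes had 10 falls and 0 rises among 14 tested, or 12 falls adjusted over the list alone, with a median log2 fold change of -3.25 (camera, adjusted p = 2.95e-14; adjusted p = 0.302 with an estimated correlation). Besides Evx1, Lhx1 fell from 109 ± 81.9 to 7.85 ± 2.66 CPM (log2 -3.79), the Nodal and BMP antagonist gene Cer1 from 54.7 ± 36.5 to 3.72 ± 2.41 CPM (log2 -3.88) and the organizer gene Gsc by 3.43 on the log2 scale. T had 240, 373 and 143 CPM in nontreated and 11.4, 33.5 and 0.271 CPM in dTAG-13 EBs and did not pass without the replicate block (log2 -4.06, adjusted p = 0.0526), but fell with it (log2 -4.6, adjusted p = 0.0132). The list had 12 falls with the block, alone or with a gene-length offset, 13 without the libraries numbered 3 and 1 without nontreated library 1 or 2 or dTAG-13 library 1. Within each group the library numbered 3 was the lowest on this list, with a mean log2(CPM + 1) of 4.37 against 5.13 and 5.71 in nontreated and 2.14 against 2.79 and 3.44 in dTAG-13 EBs. Wnt targets had 7 falls among 12, or 9 over the list alone (adjusted p = 5.64e-12; adjusted p = 0.283 with an estimated correlation), with Axin2 from 50.2 ± 6.71 to 19.2 ± 5.52 CPM (log2 -1.38), Cdx1 at -2.73 and the R-spondin receptor gene Lgr5 at -3.80. T and Sp5 are on this list and on the mesendoderm list, and Cdx2 is also on the trophoblast list, so these lists are not independent.

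**Figure D3:**
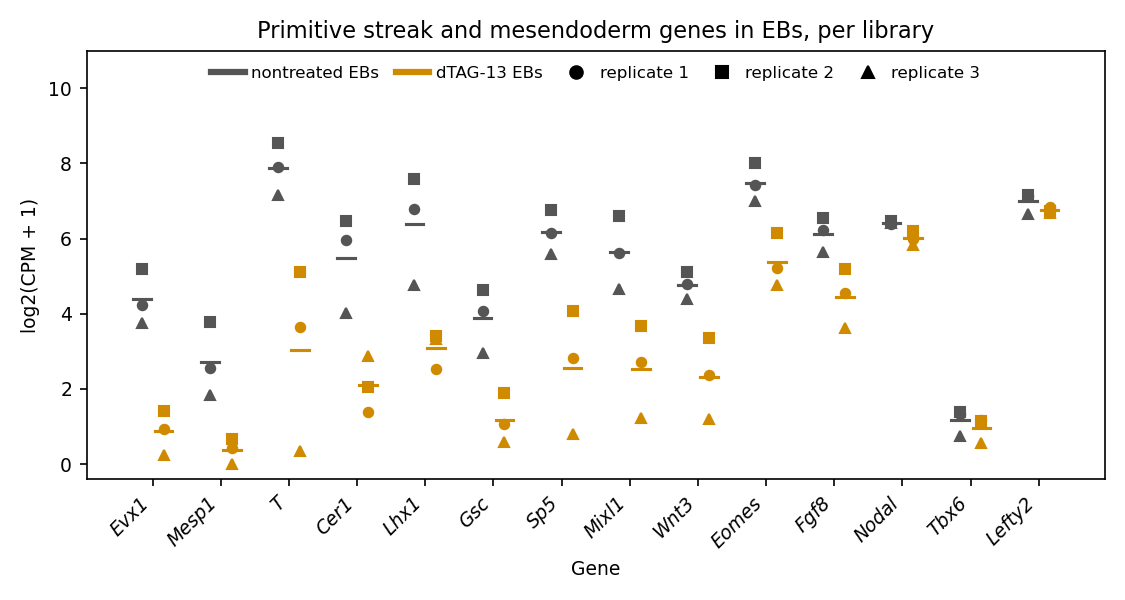
log2(CPM + 1) of the 14 tested primitive streak and mesendoderm genes in each EB library, nontreated in grey and dTAG-13 in orange, with markers for replicate numbers and bars for group means. For Evx1 the 3 dTAG-13 libraries (mean 0.928 CPM) lie below all nontreated ones (mean 21.9 CPM).

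In the lineage lists that follow, falls and no rises were called over all genes, but for 1 rise among mesenchyme genes with the replicate block. Definitive endoderm genes had 3 falls among 10, or 5 over the list alone (camera, adjusted p = 1.24e-05; adjusted p = 0.311 with an estimated correlation), with the pioneer factor gene Foxa2 from 43.6 ± 22.3 to 7.49 ± 3.35 CPM (log2 -2.54). Lateral and cardiac mesoderm genes had 4 falls among 11, or 5 over the list alone (adjusted p = 9.41e-04; adjusted p = 0.311 with an estimated correlation), with Bmp4 from 9.61 ± 3.12 to 1.65 ± 0.09 CPM (log2 -2.54), Isl1 at -4.51 and Hand1 at -2.80. Paraxial mesoderm genes had 3 falls among 10, or 4 over the list alone (adjusted p = 0.00564; adjusted p = 0.410 with an estimated correlation), Msgn1 at -5.0, Foxc1 at -3.05 and Mesp2 at -2.23. Trophoblast genes had 4 falls among 8, or 5 over the list alone (adjusted p = 3.21e-08; adjusted p = 0.283 with an estimated correlation), which were Cdx2, Esx1 at -3.25, Eomes from 185 ± 66.0 to 44.2 ± 22.9 CPM (log2 -2.06) and Hand1. Of these, Cdx2, Eomes and Hand1 are also mesoderm genes. Neural crest genes had 3 falls among 9, or 5 over the list alone (adjusted p = 5.49e-04; adjusted p = 0.311 with an estimated correlation), Twist1 at -1.89, Msx1 at -2.65 and Tfap2a at -1.85. Mesenchyme and fibroblast genes had 4 falls among 13, or 5 falls and 1 rise over the list alone (adjusted p = 0.00178; adjusted p = 0.311 with an estimated correlation), with the intermediate filament gene Vim from 229 ± 76.2 to 70.9 ± 9.77 CPM (log2 -1.69), Cdh2 at -1.81, Snai1 at -1.77 and Zeb1 at -1.56.

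Hematoendothelial genes had 4 falls and 1 rise among 13, or 6 and 1 over the list alone (camera, adjusted p = 0.00555; adjusted p = 0.283 with an estimated correlation), with Cdh5 at -1.81, Esam at -1.61, Lmo2 at -1.07 and Tek at 1.07. Nodal and BMP targets had 4 falls and 1 rise among 13, or 6 and 2 over the list alone (adjusted p = 0.0465; adjusted p = 0.497 with an estimated correlation). The Nodal antagonist gene Lefty1 rose from 103 ± 8.81 to 253 ± 38.4 CPM (log2 1.29, adjusted p = 0.00391), and Msx1, Cer1 and Id3 (log2 -0.74) fell. Cer1, Lefty2 and Nodal are also on the mesendoderm list. Extraembryonic endoderm genes had 1 fall among 20, Rhox5 at -1.26, or 3 over the list alone and 2 with the replicate block (adjusted p = 0.0128; adjusted p = 0.650 with an estimated correlation). On this list dTAG-13 EB library 3 was the highest, at a mean log2(CPM + 1) of 5.30 against 4.04 and 3.81, and nontreated EBs had 4.89, 4.64 and 4.99. Naive pluripotency genes had 7 falls among 15, or 9 over the list alone (adjusted p = 2.03e-11; adjusted p = 0.283 with an estimated correlation), with the threonine catabolism gene Tdh from 132 ± 6.99 to 74.3 ± 6.16 CPM (log2 -0.83, adjusted p = 0.00568), Zfp42 at -1.14 and Tcl1 at -1.21.

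Methylation-sensitive germline genes had 11 rises and 0 falls among 16, or 12 rises and 1 fall over the list alone, with a median of 1.13 (camera, adjusted p = 3.55e-15; adjusted p = 0.283 with an estimated correlation; fry, adjusted p = 0.0285). After Sycp3 came Taf7l at 1.85 (1.10 to 3.97 CPM), the germ cell RNA-binding protein gene Dazl from 3.95 ± 0.565 to 9.18 ± 0.444 CPM (log2 1.21) and Stk31 at 1.08. Tex19.1 was at -0.69 and did not pass over all genes without the replicate block (adjusted p = 0.0519), but fell with it (log2 -0.70, adjusted p = 0.00776). The list thus had 11 rises and 1 fall with the block, and likewise with a gene-length offset added or without the libraries numbered 3. It had 6 rises without nontreated library 2 or dTAG-13 library 1. Dazl and Ddx4 (log2 1.32) were also the 2 rises among 10 primordial germ cell genes, a list that was not called (adjusted p = 0.916; over the list alone 2 rises and 1 fall, with the replicate block 2 and 3). Integrated stress response genes had 5 rises among 15, or 6 over the list alone (adjusted p = 9.41e-04; adjusted p = 0.436 with an estimated correlation). Among them were the cystine transporter gene Slc7a11 at 1.51, Trib3 at 0.94, Atf5 at 0.76 and Ddit3 from 11 ± 2.63 to 33.9 ± 13.3 CPM (log2 1.62), which overlaps Mars on the opposite strand.

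**Figure D4:**
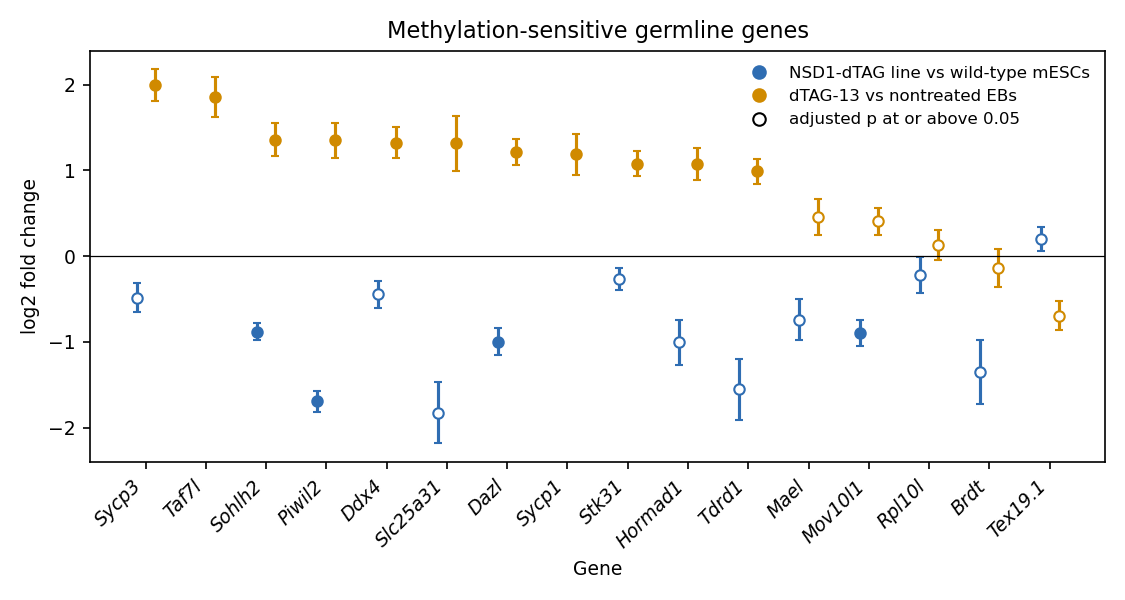
log2 fold change (± SE) of methylation-sensitive germline genes for NSD1-dTAG against wild-type mESCs (blue) and for dTAG-13 against nontreated EBs (orange), with open circles where the adjusted p was 0.05 or more. In mESCs the 4 filled points lie below 0, and in EBs the 11 filled points lie above 0.

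Smaller changes reached metabolism and growth lists. Glycolysis and hypoxia genes had 4 falls among 14, or 7 over the list alone or with the replicate block (camera, adjusted p = 4.68e-04; adjusted p = 0.311 with an estimated correlation), Bnip3 at -0.60, Pfkl at -0.49, Pgk1 at -0.45 and Eno1 at -0.39. Proliferation genes had 1 fall among 16, the ribonucleotide reductase gene Rrm2 at -0.65, or 3 over the list alone and 4 with the replicate block (adjusted p = 9.74e-04; adjusted p = 0.407 with an estimated correlation). Unfolded protein and heat shock response genes had 1 fall among 12, Hsph1 at -0.46, or 2 over the list alone or with the replicate block (adjusted p = 0.0146; adjusted p = 0.482 with an estimated correlation).

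Other lists were not called by camera in dTAG-13 EBs. Core pluripotency genes had 1 rise, Dppa4 at 0.53, and 1 fall, Tdgf1 at -0.78, among 12 (adjusted p = 0.707; over the list alone 1 and 2). Formative and primed epiblast genes had 0 calls among 10 (adjusted p = 0.642; over the list alone 0, with the replicate block 1 fall). Neuroectoderm genes had 3 falls and 1 rise among 13, over the list alone as well (adjusted p = 0.201; median 0.06, mean -0.24), with Pax6 at -1.44, En2 at -1.66, En1 at -2.77 and Neurod1 at 1.25. Surface ectoderm genes had 0 calls among 10 (adjusted p = 0.265; over the list alone 1 rise and 2 falls, with the replicate block 1 and 3), with Cdh1 at 0.45. Imprinted genes had 4 falls and 2 rises among 27 (adjusted p = 0.0971; over the list alone 8 and 3), with the noncoding RNA H19 from 10.5 ± 0.72 to 2.95 ± 0.306 CPM (log2 -1.83, adjusted p = 0.00224), Plagl1 at -1.06, Ndn at -0.83 and Impact at 0.41. Hox genes, of which 3 were tested, were not called as a list (adjusted p = 0.273). Chromatin enzymes had 1 fall among 22, the DNA methylation cofactor gene Dnmt3l at -0.62 (adjusted p = 0.987; over the list alone 1, with the replicate block 2; median 0.05, camera direction down), and degrader machinery had 0 among 6 (adjusted p = 0.866; over the list alone 0, with the replicate block 1 rise). p53 targets had 2 rises among 22, Gdf15 at 1.5 and Pmaip1 at 0.66 (adjusted p = 0.183; over the list alone 2). FGF and ERK targets had 2 falls among 12, Ier3 at -0.76 and Dusp6 at -0.39 (adjusted p = 0.0969; over the list alone 3, with the replicate block 4), and cholesterol synthesis genes had 0 calls among 14 (adjusted p = 0.916; over the list alone 0).

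In all, edgeR called 1030 of 15236 genes, 606 higher and 424 lower, 570 of them at least 2-fold, and 1834 with the replicate block, of which 1013 were among the 1030. Without nontreated EB library 1, 2 or 3 the count was 301, 182 and 1293, without dTAG-13 EB library 1, 2 or 3 it was 184, 395 and 1148, and without both libraries numbered 3 it was 3233. The excess of rises was not stable, with 628 higher and 665 lower without nontreated library 3, 1652 and 1581 without both numbered 3 and 293 and 277 at 2-fold or more. Of the 81 named calls, 46, 54 and 7 ended without nontreated library 1, 2 or 3 and 53, 28 and 7 without dTAG-13 library 1, 2 or 3. Evx1, Cdx2, Sycp3, Dazl, Bmp4, Tdh, Lefty1, Vim, H19, Lrmp, Gpnmb and Tsga10ip were called in all 16 alternatives that set no minimum fold change (Tdh changed by less than 2-fold), whereas Lhx1, Cer1, Gsc, Foxa2, Aplnr and Nanog were not, with a largest adjusted p of 0.0700, 0.0653, 0.0765, 0.0648, 0.0599 and 0.0590.

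The genes that dTAG-13 changed in EBs were sorted by a contrast of the mean of both EB groups with NSD1-dTAG mESCs, which is orthogonal to the treatment in its noise. That mean itself holds part of each gene's dTAG-13 change, which moves lowered genes towards falling and raised genes towards rising. The counts that follow therefore do not show how treatment relates to differentiation. In that contrast 5692 of 15741 genes rose and 5066 fell. Of genes rising in differentiation, 228 were lowered and 410 raised by dTAG-13, and of genes falling in differentiation, 131 were lowered and 107 raised. The share of lowered genes that rise in differentiation was 53.8%, against 67.7% of raised genes, and 38.2% of these calls went against the direction of differentiation (odds ratio 2.2, Fisher's exact test across genes, two-sided p = 3.12e-07, with genes that are not independent). Without nontreated EB library 2 the odds ratio was 1.81 (Fisher's exact test, p = 0.135), and with nontreated EBs alone against mESCs, a contrast free of that part but sharing its EB libraries with the treatment comparison, it was 0.81 (p = 0.207).

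Wild-type mESCs and EBs of the tagged line were also compared in their response to dTAG-13, which combines the difference of stage, genotype and duration. The culture medium may differ too, since the mESCs were kept in 2i/LIF with its GSK3 inhibitor. Cdx2, Evx1 and T differed most on the negative side, at -5.55, -5.13 and -4.44 on the log2 scale (adjusted p = 1.07e-04, 0.00299 and 0.0384). Evx1 had only 1.26 and 1.90 plain CPM in nontreated and treated wild-type mESCs, so a fall could hardly show there. Leaving out single libraries ended the call of T in 9 of 12 cases (largest adjusted p = 0.116). The Wnt target gene Sp5 differed by -3.59 (adjusted p = 0.0257), a call that ended in 8 of 12 such cases (largest adjusted p = 0.0797). It was at 76.1 and 92.8 CPM in nontreated and treated wild-type mESCs and at 71.6 and 7.22 CPM in nontreated and treated EBs. Wnt targets had 7 negative calls among 12, or 8 over the list alone (camera, adjusted p = 1.11e-16; adjusted p = 0.0486 with an estimated correlation), and 13 lists were called with the preset correlation. The other 12 of these calls ended with an estimated correlation (adjusted p of at least 0.0534). Levels of some Wnt targets differed between these cells without dTAG-13. Axin2 had 119 plain CPM in nontreated wild-type mESCs and 49.9 in nontreated EBs, and Notum had 105 and 5.65. Lef1 was lower in the mESCs, at 21.8 and 62.2 CPM. Of the genes called for dTAG-13 in EBs, 771 were also tested in wild-type mESCs. Among these, 32 (4.15%) had an unadjusted p below 0.05 there, against 229 of 13784 (1.66%) over all genes. Both lie under the share of 0.05 that unchanged genes give on average, so they do not show a response there. The same sign was found in 13 of the 32 and in 45.5% of the 771. The median absolute log2 change was 0.93 in EBs, for which the genes were selected, and 0.08 in wild-type mESCs. The interaction called 402 of the 771.

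For the interaction as a whole, edgeR called 456 of 15855 genes, 254 positive and 202 negative. This balance turned with a gene-length offset (296 and 316), with no low-count filter (447 and 468) and without the libraries that stand apart (933 and 964). The count was 265, 208 and 202 without wild-type nontreated library 1, 2 or 3, 228, 245 and 274 without wild-type dTAG-13 library 1, 2 or 3, 238 and 763 without nontreated EB library 2 or 3 and 260 without dTAG-13 EB library 1.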

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

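The comparison with wild-type mESCs for the mesendoderm genes was chosen after that result was seen, as were the gene-length offset, that offset with the replicate block, the fit without libraries that stand apart and the sorting of splits by EB label, while the other tests were chosen before. The interaction count, the single genes and the Wnt targets here stood out because a test of the difference found another response to dTAG-13 in EBs of the tagged line than in wild-type mESCs, and stage, genotype and duration of treatment all differ between these. The mesendoderm and germline lists were added for a closer look and were not flagged as lists by that test. The mESC part of the germline result involves no dTAG-13.

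The interaction called 456 genes (edgeR). Of 80 splits of the libraries with the same group sizes, 5 gave at least as many calls, the real one included, and the highest of the others gave 584, so that chance was not excluded by this count. The 6 other splits that kept the EB labels gave 372 to 584 calls, and the 73 that mixed EB labels gave 0 each, so the count follows the EB labels.

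Negative differences on the log2 scale were largest for Cdx2 at -5.55 (adjusted p = 1.07e-04), Evx1 at -5.13 (adjusted p = 0.00299), T at -4.44 (adjusted p = 0.0384), Nog at -4.12 (adjusted p = 0.0475), Slc44a5 at -3.93 (adjusted p = 0.0421), Esx1 at -3.78 (adjusted p = 0.00173), Pglyrp1 at -3.74 (adjusted p = 6.94e-04) and Sp5 at -3.59 (adjusted p = 0.0257). Positive differences were largest for Fut1 at 4.10 (adjusted p = 0.0435), Tsga10ip at 3.48, Fndc1 at 2.97 (adjusted p = 0.0375), Gpnmb at 2.95, Lrmp at 2.84, Zfp783 at 2.82, Zfy1 at 2.47 and Hormad2 at 2.41. Nanog differed by -0.77 (adjusted p = 0.0142). Some of these genes were barely expressed in wild-type mESCs. Without and with dTAG-13, Evx1 had 1.26 and 1.90 plain CPM there and Slc44a5 0.505 and 0.510, whereas Lrmp had 22.0 and 22.5. For genes that low a fall could hardly show in wild-type mESCs, so the difference mostly restates the change in EBs. Wnt targets differed by a median of -1.43 over 12 genes, with 7 negative and 0 positive calls, and passed camera with the preset and the estimated correlation (adjusted p = 1.11e-16 and adjusted p = 0.0486). The list holds Cdx2, T and Sp5, which are named above, so it is not a separate result. Leaving out single libraries ended the calls of T, Nog, Slc44a5, Sp5, Fut1 and Fndc1 in 8 to 11 of 12 cases (largest adjusted p = 0.116, 0.248, 0.146, 0.0797, 0.206 and 0.167) and of none of the other genes named here.

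Primitive streak and mesendoderm genes were lower in dTAG-13 EBs, by a median of -3.25 (14 genes, SE over members 0.41, which takes genes as independent; camera, adjusted p = 2.95e-14; adjusted p = 0.302 with an estimated correlation). The median was -3.39 with a gene-length offset and the replicate block. Read-weighted exon lengths were close in nontreated EBs (5.81, 5.84 and 5.48 kb) and dTAG-13 EBs (5.93, 5.92 and 5.50 kb). The offset thus had little length trend between the groups to remove and could hardly have removed the difference. The median was -3.05 without the libraries numbered 3. Those were the lowest on this list in both groups, so leaving them out could hardly remove a difference between the groups. The value shows only that the remaining libraries hold the difference. A response to dTAG-13 that needs no tag and has the same size in mESCs is opposed only for the 8 members tested in wild-type mESCs. Their median was 0.0228 (SE 0.0978). Other members of the list did not reach the count filter there and could not be judged, so this median and that in EBs cover different sets of genes. Also open is a response to dTAG-13 itself that arises only in EBs, because wild-type EBs were not analysed here, and a different timing or share of cell types between EB cultures. Loss of tagged NSD1 may lower these genes in EBs, as a hypothesis that came from these data and was not itself tested. Wild-type EBs with and without dTAG-13 would show only whether the compound lowers them without the tag.

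Methylation-sensitive germline genes were lower in NSD1-dTAG than in wild-type mESCs (median -0.89, SE over members 0.16, 14 genes; camera, adjusted p = 0.112 with an estimated correlation) and higher in dTAG-13 than in nontreated EBs (median 1.13, SE 0.18, 16 genes; adjusted p = 0.283 with an estimated correlation). With a gene-length offset and the replicate block the medians were -0.91 and 1.14. Between the EB groups, close in read-weighted exon length, the offset had little to remove. In mESCs these lengths were 5.43, 5.72 and 5.73 kb in wild-type and 4.99, 5.74 and 5.78 kb in NSD1-dTAG libraries. There the kept median argues against gene length as the whole cause. Without the libraries that stand apart the medians were -0.87 and 1.05. Each group compared holds such a library, so leaving them out shows only that the remaining libraries hold the differences. Counts of called members moved in these fits, from 4 falls to 10 falls and to 10 falls and 1 rise in mESCs, and from 11 rises to 11 rises and 1 fall in EBs in both, and leaving out any 1 wild-type library ended all 4 mESC calls. The mESC difference exists without dTAG-13 and may belong to the tag, the clone or its passage, which the groups cannot part. The EB difference could come from loss of tagged NSD1 or from dTAG-13 in EBs, and no DNA methylation was analysed here.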

How the results depend on the processing

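The gene-length offset, that offset with the replicate block and the fit without the libraries that stand apart were chosen after seeing the data, and the other alternatives before. The planned counts on another strand were not run, because each table holds 1 count column, and ERCC scaling was not run where EBs enter, because their ERCC counts are 0. For dTAG-13 in wild-type mESCs the count stayed 0 in every alternative chosen before and was 16 without the libraries that stand apart. For the NSD1-dTAG line against wild-type (259) it was 636 with DESeq2, 1 with ERCC scaling, 500 with all 15 libraries in one fit, 110 at 2-fold or more, 785 with the replicate block, 650 with the gene-length offset, 1388 with both, 3123 without the libraries that stand apart and 1 to 1248 when single libraries were left out. For dTAG-13 in EBs (1030) it was 1686 with DESeq2, 1931 with all 15 libraries, 570 at 2-fold or more, 1834 with the replicate block, 1830 with the block and gene-length offset, 3233 without the libraries numbered 3 and 182 to 1293 when single libraries were left out. For EBs against mESCs (9037) it was 5290 at 2-fold or more and 7999 with the replicate block. For the interaction (456) it was 799 with DESeq2, 915 with no low-count filter, 288 at 2-fold or more, 1897 without the libraries that stand apart, 537 with the replicate block and 202 to 763 when single libraries were left out. The odds ratio of treatment against differentiation calls (2.2) turned to 0.81 with nontreated EBs alone against mESCs, a contrast that shares its EB libraries with the treatment while the main one holds part of the treatment's change, and was 1.81 (Fisher's exact test, p = 0.135) without nontreated EB library 2, within 1.80 to 3.71 when single libraries were left out. The cause was not tested, except that a size threshold makes calls fewer by construction. Leaving out single libraries gave fewer calls in some fits and more in others, up to 1248 between the mESC lines, 1293 for dTAG-13 in EBs and 763 in the interaction. No named gene or list reversed among those called in the main fit or in the alternative. Signs of genes and lists called in neither were not compared. Leaving out single libraries ended at most 3 of the 17 list calls for dTAG-13 in EBs, 2 of the 8 between the mESC lines, 3 of the 4 in wild-type mESCs, 2 of the 14 between EBs and mESCs and 1 of the 13 in the interaction. For dTAG-13 in EBs, limma-voom ended 9 of the 81 named gene calls, and fry ended 16 of the 17 list calls, all but that of germline genes (adjusted p = 0.0285). In the interaction limma-voom ended 11 of 50 named gene calls, and fry ended 7 of 13 list calls and added 1. In wild-type mESCs fry ended all 4 list calls. It ended 0 of 8 between the mESC lines and 0 of 14 between EBs and mESCs, and added 5 and 11 there. With an estimated correlation no list stayed called but Wnt targets in the interaction. Where the replicate numbers pair the samples, the block added Bmp4 (adjusted p = 0.0393) and the lateral and cardiac mesoderm (adjusted p = 0.0478) and neural crest lists (adjusted p = 0.0299) to the calls between the mESC lines and Cdh1 (adjusted p = 0.0476) to the EB calls. It also added T, Tex19.1 and Mest to the latter and, in both comparisons, other list members, which the text counts where their number moved most, and it changed no other call of a list or of a gene that the rule named there. In the interaction the EB libraries correlate by number (0.21, 0.25 and 0.36) and the wild-type ones do not (-0.15, 0.14 and -0.14). There the block ended 1 of 50 named gene calls and no list call. In the remaining comparisons samples share only a number: same-numbered libraries correlated at -0.29, 0.23 and -0.25 for wild-type mESCs and -0.20, 0.13 and -0.27 for EBs against mESCs, not each closest to its own number. The gene-length offset ended the calls of Nodal and BMP targets in EBs (adjusted p = 0.087) and Hox genes between the mESC lines (adjusted p = 0.080) and of neural crest genes in the interaction (adjusted p = 0.0556). With the block added it ended those of Hox (adjusted p = 0.149) and naive pluripotency genes (adjusted p = 0.0520) between the mESC lines. Of named gene calls the offset ended those of Tdgf1 in EBs (adjusted p = 0.063), Nsd3, Crbn and Ddb1 between EBs and mESCs (the calls of Nsd3 and Ddb1 also ended in 4 of 6 fits without a single library) and Gsc in the interaction (adjusted p = 0.0516). Simulated 1.5-fold changes were found in 71.6% of cases for dTAG-13 in wild-type mESCs, 20.9% between the mESC lines and 19.4% for dTAG-13 in EBs, where the biological coefficient of variation was 0.0889, 0.140 and 0.151, and depth was not varied in these simulations. They hold no shift shared by the genes of a library, so these shares may not describe the power of the real comparisons.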

Other observations

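The test of Mest in EBs and the simulation of unchanged groups were chosen after the result was seen, and the other tests here before. Extraembryonic endoderm markers set the EB libraries apart in another way than the mesendoderm genes. Their mean log2(CPM + 1) was 4.89, 4.64 and 4.99 in nontreated EBs and 4.04, 3.81 and 5.30 in dTAG-13 EBs, so that dTAG-13 library 3 stood above all nontreated libraries while libraries 1 and 2 stood below them. Definitive endoderm markers stood at 4.46, 4.80 and 3.58 in nontreated and 2.78, 3.03 and 3.23 in dTAG-13 EBs. The share of mitochondrial counts was also lowest in the libraries numbered 3, at 0.199% in nontreated and 0.237% in dTAG-13 EBs, against 0.425% to 1.11% in the other 4.

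The median fold change of genes by chromosome stayed close to that of the other chromosomes in both dTAG-13 comparisons, within 0.02 in wild-type mESCs and 0.04 in EBs on the log2 scale. Between NSD1-dTAG and wild-type mESCs chromosome 8 stood at -0.06 and chromosome 14 at 0.06, and between EBs and mESCs chromosome 14 at 0.16 and chromosome X at 0.36.

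Mest was close to silent in NSD1-dTAG mESCs, which had received no degrader, and 259 genes differed between that line and wild-type mESCs. Chance values of the wild-type nontreated libraries are opposed by the other controls: against wild-type dTAG-13 mESCs a median of 90.8% of the fold change was kept over the 256 called genes tested there, all with the same sign, with 99 of them called. Both comparisons use the same NSD1-dTAG libraries, so chance values of those are not opposed. In 20 simulations of unchanged groups, the 259 genes with the smallest p kept a median of 50.7% (47.2% to 54.4%) and had the same sign in 90.2% of cases (86.0% to 92.5%). Whether Mest stayed silenced through differentiation cannot be told apart from a normal level in EBs, since wild-type EBs were not analysed here: Mest rose from 0.546 to 3.26 CPM between mESCs and nontreated EBs of the line (log2 2.41, edgeR adjusted p = 1.72e-04), and its highest nontreated EB library had 4.06 CPM against a wild-type mESC mean of 29.5 CPM. Neither alleles nor methylation were analysed here. Whether the tag or the history of the line carries the other differences stays open, since 1 knock-in line was analysed here.

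For the comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. As many genes as in the real split came from 10 of 10 splits for dTAG-13 in wild-type mESCs, where the real and the highest other count were 0. It was 1 of 10, the real split, for the NSD1-dTAG line against wild-type mESCs (259, highest other 0), for dTAG-13 in EBs (1030, highest other 0) and for EBs against mESCs (9037, highest other 0). Where the numbers pair the samples, 3 other splits part all pairs as the real one does, and they gave 0 calls.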
